A study of Mus musculus with 12 samples.

How the data were processed

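Pituitary RNA from 12 female mice of the inbred C57BL/6J strain, aged 2 months, was compared on Agilent 2-colour mouse arrays. The labels place 4 animals in each of 3 diet groups and describe them as biological replicates. Each of the 6 arrays carried 2 animals of a single group, the odd-numbered animal labelled with Cy3 and the even-numbered with Cy5.

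The deposited scanner files give spot brightness as raw intensity, from Agilent Feature Extraction 11.0.1.1 per the file headers, together with background intensity, quality marks and a processed intensity that the software had background-subtracted and dye-normalized. The deposited value table gives log2 values. In its 8 columns of the deficient groups they equal the median spot brightness less the median local background, taken relative to the median of that difference in the column, so that column medians are 0. The authors' labels do not describe this step. The raw intensity was used for the comparisons. The value table served as an alternative for the comparison of both deficient groups, and its columns were matched to the scanned channels within a tolerance of 1e-06 on the log2 scale.

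Each array held 44397 features, of which 1377 were control features and were left out, as were spots that the software had marked as outliers. Background was corrected by normexp with an offset of 50, dye bias was removed within arrays by loess, and arrays were brought to a common mean intensity distribution by the Aquantile method. Single-channel log2 values followed from these steps. Replicate spots of a probe were averaged, which gave 39429 probes. Probes were kept where they were well above background in at least 4 of the 12 channels, which left 24605. Of all probes, 27234 were matched to gene symbols by accession, 3576 by symbol and 565 by synonym, while 8054 were unmatched and kept the name in the file. The probe with the highest mean stood for its gene, which gave 19090 genes in the fit, 15622 of them with a symbol in the reference table. Probe positions are those of mouse build mm9 per the file headers. No genome sequence was used, so probes were not realigned.

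Groups were compared with the model of limma, with group and dye as fixed terms and array as a random block. It was computed gene by gene, so that genes missing an array used the samples they had, and was checked against limma's own output on genes with all values. The estimated correlation between animals on 1 array was 0.342, and the fit had 8 residual degrees of freedom and a prior of 3.38. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. All tests of genes were two-sided. A spot marked as an outlier is lost for both animals of an array, so 4706 genes lacked a value on at least 1 array and the n of such genes is smaller. Where all 4 samples of a group were not well above background, the fold is given as a lower bound. For it, each sample of that group was raised to the lowest value of a probe well above background in its channel where it lay under that value.

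Altogether 47 gene lists were fixed, covering hormone cell types, other cell types of the gland and its surroundings, and pathways, and 46 had at least 5 measured genes. They were tested with limma's camera on the moderated statistics with a preset correlation of 0.01, again with a correlation estimated per list, and with fry, each adjusted over the lists of a comparison. Scores per animal are the mean log2 deviation of a list's members from their mean over all samples. They were compared by exact two-sided permutation tests.

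Genes were named by a rule fixed before the data were examined. Within each comparison it takes the 10 largest positive and 10 largest negative log2 differences among genes past the threshold whose groups do not overlap, counting only symbols of the reference table and no predicted gene models. Where fewer than 10 pass, the 10 genes of smallest p are named too and stated as not passing. Vdr, Cyp24a1, Gh, Prl, Pomc, Lhb, Fshb, Tshb and Cga are always named, as are the 4 members of smallest p of each list past the threshold. Some genes that the rule takes are counted but not reported here. The comparisons, lists and most alternative settings were also fixed before the data were examined.

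The steps were tested on simulated data with the spread and array correlation of the real data and known changes added to randomly chosen genes. Of the genes given a log2 change of 1, the fit recovered 67.7% for early life against control, 83.3% for peripubertal against control and 78.1% for early life against peripubertal. For a change of 2 it recovered 96.9%, 92.5% and 92.3%. False calls made up 15 of 182, 15 of 196 and 20 of 194 calls, which is above the nominal 5%. The number of arrays limits the precision of every value, and the median standard error of a log2 difference was 0.19 in each comparison.

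To look for raised or lowered patches of an array, the dim spots within 2 positions of each spot were averaged as deviations from their medians over the arrays, where at least 3 were present. The spots around called genes were compared with those of 10000 random sets of genes of like brightness by a one-sided permutation test, and an alternative left out spots whose neighbours deviated by more than 0.3. Random sets were drawn without regard to position, so the test takes overlapping neighbourhoods of close spots as independent.

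Alternatives covered background correction, scaling between arrays, filters, the treatment of probes, arrays and dyes, and the omission of each sample and array in turn. Analyses used R 4.3.3, limma 3.58.1, statmod 1.5.0, jsonlite 2.0.0 and the data.table package (version 1.17.8). Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.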

Results

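Pituitary glands came from 12 adult female mice that had eaten a control diet or had lacked dietary vitamin D either early in life or around puberty, with 4 mice in each of the 3 groups. The question is how each window of deficiency changes the gland's transcripts at 2 months of age. Each of the 6 arrays carried 2 animals of the same group in different dyes, so array-mates were not independent. Both control arrays lay on 1 slide from 1 scan session and the other 4 arrays on another, so slide and diet cannot be told apart in any comparison with control. Both deficient groups shared a slide. The share of spots well above background ran from 61.0% to 66.3% in control, from 50.6% to 59.7% in early life and from 57.9% to 67.2% in peripubertal samples. Outlier marks removed 1.68% to 1.90% of spots on control arrays, 6.54% to 7.34% on early life arrays and 3.85% to 5.08% on peripubertal arrays. The number of arrays limits the precision of every value.

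The files disagree on which deficient group is which. All 8 columns of the deficient groups in the authors' value table equal a scanned channel filed under the other deficient group, within 1e-06 on the log2 scale. Group names here follow the scanner files. Under the value table's assignment, every value given for early life belongs to the peripubertal group and the reverse, and the files do not settle which assignment is right. The table's 4 control columns equal no scanned channel, so the control values here come from scanner files that the table does not hold.

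Gh, Prl, Pomc and Cga ranked between 1 and 24 in brightness on every array that measured them, Tshb between 1017 and 1905 and Lhb between 1561 and 3967. None of the main hormone genes differed between groups by the test. Prl, which encodes prolactin, averaged 18.03 ± 0.17 (log2, SD, n = 4) in early life, 17.75 ± 0.60 in control and 17.61 ± 0.46 in peripubertal samples. Pomc, the precursor of ACTH, averaged 17.63 ± 0.70, 17.44 ± 1.03 and 17.90 ± 0.43 in the same order, and Tshb, the beta chain of thyrotropin, 14.04 ± 0.54, 13.76 ± 0.43 and 13.99 ± 0.62. All Pomc values in Cy5 (18.07 to 18.46) lay above those in Cy3 (16.47 to 17.59). The SDs of Pomc therefore include a dye difference, which the fit takes into account. Lhb, the beta chain of luteinizing hormone, averaged 12.91 ± 0.44, 12.94 ± 1.18 and 13.66 ± 0.67. Cga, the chain shared by these glycoprotein hormones, averaged 17.40 ± 0.55 over 2 early life samples, 17.41 ± 0.48 in control and 17.59 ± 0.29 in peripubertal samples. Gh, which encodes growth hormone, averaged 18.30 ± 0.64 over 2 early life samples, 18.30 ± 0.20 in control and 18.08 ± 0.50 in peripubertal samples. It was the brightest gene on 4 of the 5 arrays that measured it, so the scaling between arrays sets its mean there by rank. Fshb, the beta chain of follitropin, averaged 14.34 ± 0.89 in control and 15.01 ± 0.27 in peripubertal samples and had no value in early life, where its spots were marked as outliers. Adjusted p-values ran from 0.683 for Prl to 1.00 for Gh for early life against control, from 0.470 for Prl to 0.954 for Tshb for early life against peripubertal, and were 1.00 for all of these hormone genes for peripubertal against control. Under other scalings the small differences of Lhb, Pomc and Cga changed sign in at least 1 comparison. With the mean of a gene's probes in place of the brightest, Cga differed by -2.80 for early life against control and by -2.93 against peripubertal, also without passing. The brightest Cga probe had no value in early life 1 and 2, so the mean there rests on its other probes. These differences therefore compare unlike sets of probes.

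Vdr, the vitamin D receptor, averaged 9.57 ± 0.35 (log2, SD, n = 4) in early life, 8.43 ± 0.49 in control and 8.69 ± 0.10 in peripubertal samples. All 4 early life values lay above the 8 others, but neither difference passed the test. The log2 difference was 1.14 (SE 0.25, adjusted p = 0.130) against control and 0.88 (SE 0.25, adjusted p = 0.128) against peripubertal. Vdr differed by 0.26 between peripubertal and control (SE 0.25, adjusted p = 1.00). Cyp24a1, the enzyme that breaks down active vitamin D, did not stay in the data after the filter on dim probes. Of 24 measured genes in the list of vitamin D targets and metabolism, 15 were higher and 9 lower in early life than in control, with a median log2 difference of 0.19 (camera adjusted p = 0.590). Against peripubertal the median was 0.13 (camera adjusted p = 0.807), and between peripubertal and control it was 0.00 over 25 genes (camera adjusted p = 0.852). Lists of somatotroph, lactotroph, gonadotroph, thyrotroph, corticotroph and melanotroph markers did not pass in any comparison. Their adjusted p-values ran from 0.271 (lactotroph) to 0.814 (corticotroph) for early life against control, from 0.271 (somatotroph) to 0.852 (lactotroph) for peripubertal against control, and from 0.273 (lactotroph) to 0.973 (gonadotroph) for early life against peripubertal.

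**Figure D1:**
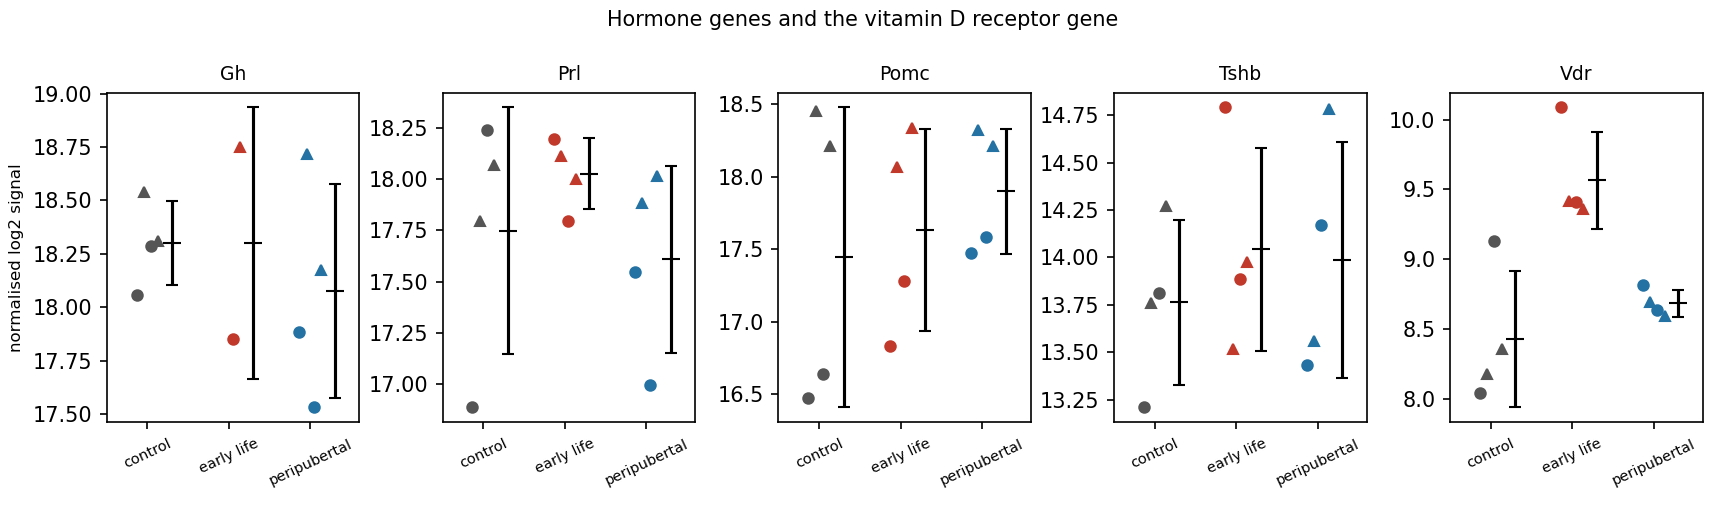
Log2 intensity of Gh, Prl, Pomc, Tshb and Vdr in each animal, by diet group, with circles for Cy3, triangles for Cy5 and bars for the mean and SD. The hormone genes overlap between groups, while the 4 early life values of Vdr lie above the others.

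For early life deficiency against the control diet, the largest differences past the threshold included genes that were higher and genes that were lower. Nox4, an oxidase that produces hydrogen peroxide, averaged 8.77 ± 0.38 (log2, SD, n = 4) against 6.50 ± 0.10 in control. This is at least 3.75-fold higher, since no control was well above background (log2 difference 2.27, SE 0.18, adjusted p = 0.000529). Trmo, a tRNA methyltransferase, was at least 6.65-fold higher (log2 difference 2.79, SE 0.30, adjusted p = 0.00583), Bpifb9b at least 4.14-fold (adjusted p = 0.00823), and Ulbp1, a ligand of the NKG2D receptor of natural killer cells, at least 3.26-fold (adjusted p = 0.00583). Sensory receptor genes were among them, with a log2 difference of 2.27 for the odorant receptor Olfr1219 (adjusted p = 0.000774) and at least 2.32-fold for the vomeronasal receptor Vmn1r211 (adjusted p = 0.0311). Adam4, of the ADAM family of membrane proteins, averaged 10.83 ± 1.04 in control and 6.89 ± 0.06 in early life, at least 11-fold lower (adjusted p = 0.0330). Uap1, an enzyme that makes UDP-N-acetylglucosamine, was lower with a log2 difference of -1.44 (adjusted p = 0.0348), from 2 early life samples. The odorant receptor Olfr1535 was lower, with a log2 difference of -1.12 (adjusted p = 0.0266), and Myo5c, an unconventional myosin, was at least 1.84-fold lower (adjusted p = 0.0346). The probe of Nox4 lies on chromosome 7 at 94547113 to 94547172, that of Trmo on chromosome 4 at 46389847 to 46389906 and that of Olfr1219 on chromosome 2 at 88914406 to 88914465.

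In all, 18 of 18387 genes passed for early life against control, 10 higher and 8 lower, and 11 of them have a gene symbol of the named kind. None of these 18 had overlapping groups. Chance gives this to 2.86% of unselected genes with 4 independent values per group. The 18 were selected on the same values, so the lack of overlap adds no support. An unadjusted p under 0.05 was reached by 2971 genes, where 919 would reach it by chance, and 3 of the 35 splits of these samples gave as many, with 4287 in the highest other. Nox4 and Olfr1219 lie on touching spots of the array, in rows 66 and 67 of column 11. Ulbp1 lies in row 306 of column 72, near higher spots in rows 305 and 307 of column 69. Vmn1r211 and Trmo lie in rows 307 and 308, in columns 81 and 57. Around all 10 of the higher spots, the dim neighbouring spots were brighter in early life too, by a mean log2 difference of 0.30 (SD 0.12), a size that 0 of 10000 random sets of spots reached (permutation p = 0.0001, the smallest this number can give). Around the 8 lower spots they differed by -0.27 (SD 0.61, permutation p = 0.0009), with 5 of 8 lower. Adam4 (-1.06) and the spot diagonal to it (-1.42) carry this mean, and the other 6 averaged 0.048 (SD 0.14). The other 2 probes of Nox4, which were too dim to be kept, differed by -0.10 and -0.09. The other probe of Ulbp1, also too dim to be kept, differed by -0.01. The other kept probe of Trmo differed by -0.16, and with the software's processed signals that probe stood for the gene and gave -0.69. Without spots in such patches at a limit of 0.3, an alternative added after seeing the data, Nox4, Olfr1219, Trmo and Adam4 had no estimate. Of the other 7 genes under the naming rule 5 passed, among them Ulbp1 with all 12 channels kept (adjusted p = 0.00931) and Bpifb9b with 10 (adjusted p = 0.0347). The calls of Olfr1535 and Vmn1r211 ended with 10 channels left, at -1.03 (SE 0.20, adjusted p = 0.0960) from -1.12 (SE 0.16) and at an unchanged 1.63 (SE 0.25, adjusted p = 0.0537) from an SE of 0.24. On the early life arrays the dim spots around Ulbp1 deviated by 0.21 and 0.26, and those around Bpifb9b by 0.25 and 0.50. At a limit of 0.2 neither gene therefore had an estimate. The count of 18 became 7, 9, 227 and 6 without control 1, 2, 3 or 4 and 280 without early life 3. It was 0 among genes well above background in all 12 channels and 4 (3 higher, 1 lower) with median centring.

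No gene list passed for early life against control, with 46 tested by camera, and 0 with an estimated correlation or with fry. The closest 7 shared an adjusted p of 0.0826. Medians were positive for activin and inhibin signalling (0.29 over 18 genes), glucocorticoid-responsive genes (0.65 over 13), immediate early genes (0.57 over 20) and cell cycle genes (0.27 over 23). They were negative for erythroid genes (8 of 10 negative), complement (-0.54 over 12) and cholesterol synthesis (-0.30 over 20). With an estimated correlation the smallest adjusted p was 0.927, with 0 lists under an unadjusted p of 0.05, and with fry it was 0.441, with 4 such lists. Without control 3, 7 lists passed, without early life 1 it was 5, without control 1 it was 2 and without early life 3 it was 1.

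For peripubertal deficiency against the control diet, 4 genes passed and all were lower, while a fit of only the 8 samples compared called 10, of which 7 were higher and 3 lower. Zfyve9, an endosomal adaptor of TGF-beta signalling, averaged 7.43 ± 0.21 (log2, SD, n = 4) against 8.75 ± 0.17 in control, a log2 difference of -1.32 (SE 0.17, adjusted p = 0.0450). Its probe lies on chromosome 4 at 108311864 to 108311923. Tatdn2, of the TatD family of nucleases, averaged 7.11 ± 0.12 against 8.38 ± 0.20, a log2 difference of -1.26 (SE 0.16, adjusted p = 0.0450). The others, picked out after their values were seen because the rule skips unnamed transcripts, were TC1711418 (log2 difference -1.11, SE 0.15) and ENSMUST00000139309 (-3.60, SE 0.47), which lies on the spot diagonal to Adam4. The dim spots around all 4 differed by -0.31 (SD 0.56, permutation p = 0.0049), which that spot carries alone (-1.14). Around the other 3 they averaged -0.033 (SD 0.050), with Zfyve9 at 0.02 and Tatdn2 at -0.04. The remaining 8 of the 10 genes of smallest p did not pass, with adjusted p-values from 0.187 to 0.201. Among them were the splicing factor Prpf19 (-0.79), the ubiquitin hydrolase Uchl3 (-0.74), the repressor Tgif2 (-0.94), the ubiquitin ligase Ube4a (-1.02), Rtl5 (-1.28, from 2 peripubertal samples), the clathrin adaptor subunit Ap2b1 (-1.39) and Adam4 (-3.09).

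These 4 were called among 18771 genes, of which 880 had an unadjusted p under 0.05 where 939 would by chance. The count was 0 without control 1, 2 or 3, without any 1 of the early life samples, and without peripubertal 1, 3 or 4, and it was 1 without control 4. It was also 0 with a normexp offset of 16, quantile scaling, median centring, no filter on dim probes or array means.

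Of the fixed lists, 4 passed for peripubertal against control with the preset correlation, all upward, and 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) or with fry (0). For MHC and antigen presentation, 13 of 16 genes were positive with a median of 0.40 (camera adjusted p = 0.00105; adjusted p = 0.918 with an estimated correlation). Examples are the class II genes H2-DMa at 1.12, H2-Ab1 at 1.05 and H2-Eb1 at 0.93, and B2m, the light chain of class I, at 0.81, of which H2-Ab1, H2-Eb1 and B2m rest on peripubertal 3 and 4 alone. MHC scores were 0.28 and 1.04 in these samples and -0.08 and -0.17 in peripubertal 1 and 2. Without the array of peripubertal 3 and 4 the MHC list turned direction by its test. Macrophage scores were also higher in peripubertal 3 and 4 (0.71 and 0.42) than in 1 and 2 (0.08 and -0.31), and 13 of 14 macrophage genes were above control with a median of 0.26 (camera adjusted p = 0.205). All 10 erythroid genes were positive with a median of 0.78 (camera adjusted p = 0.00812; adjusted p = 0.918 with an estimated correlation), among them Hba-a2 at 1.05, Hbb-bt at 0.97, Hba-a1 at 0.94 and Ahsp, a hemoglobin chaperone, at 0.77. Erythroid scores in control went with the array, at 0.97 and 0.68 in controls 1 and 2 and at -0.81 and -0.62 in controls 3 and 4. Without the array of controls 3 and 4 the list turned direction by its test (median 0.034). All 21 interferon-response genes were positive with a median of 0.25 (camera adjusted p = 0.00812; adjusted p = 0.918 with an estimated correlation), among them Gbp2 at 0.82 (11.80 in peripubertal 4 and 9.61, 9.79 and 9.63 in the others, against a control mean of 9.39), Irf9 at 0.59, Stat2 at 0.55 and Ifit1 at 0.40. For glycolysis 16 of 19 were positive with a median of 0.21 (camera adjusted p = 0.0444; adjusted p = 0.671 with an estimated correlation), among them the glucose transporter Slc2a3 at 0.35, Pfkl at 0.26, Pfkm at 0.21 and Gpi1 at 0.17. No member passed over all genes, and 3 MHC genes and 0 genes of the other lists passed when adjusted over the list alone. Without peripubertal 4 the MHC list (adjusted p = 0.226) and the interferon list (adjusted p = 0.379) no longer passed, and the erythroid list did not pass without control 3 (adjusted p = 0.156) or peripubertal 3 (adjusted p = 0.0994). Glycolysis passed in 3 of 12 fits that left out 1 sample, with an adjusted p up to 0.223 without peripubertal 1, and the count of lists was 8 without control 2, 7 without peripubertal 2, 2 without peripubertal 3 and 1 without peripubertal 4.

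Early life against peripubertal deficiency is the comparison made within 1 slide. Of the 16 genes that passed under the naming rule, 7 were higher in early life. These were Olfr1219 (at least 4.76-fold, adjusted p = 0.000534), Nox4 (at least 4.05-fold, adjusted p = 0.000534), Ulbp1 (at least 3.55-fold, adjusted p = 0.00248), Trmo (at least 6.72-fold, adjusted p = 0.00347), Bpifb9b (at least 4.42-fold, adjusted p = 0.0109), Vmn1r211 (at least 2.63-fold, adjusted p = 0.0422) and Cltrn, a partner of amino acid transporters (log2 difference 1.29, adjusted p = 0.0476). The others were lower in early life. Plxna4, a semaphorin receptor, averaged 9.90 ± 0.14 (log2, SD, n = 4) against 10.99 ± 0.14, a log2 difference of -1.09 (SE 0.14, adjusted p = 0.0368), with its probe on chromosome 6 at 32094602 to 32094661. Sdc3, a cell-surface heparan sulfate proteoglycan, averaged 9.66 ± 0.19 against 10.84 ± 0.09, a difference of -1.18 (SE 0.18, adjusted p = 0.0368). Erfe, the erythroid hormone that lowers hepcidin, was at least 2.09-fold lower (adjusted p = 0.0422), and Plet1 at least 1.31-fold (adjusted p = 0.0460). Tmsb10, an actin-binding thymosin, differed by -1.43 (adjusted p = 0.0476), from 2 early life samples. Cfap161, a cilium protein, differed by -1.42, the calcium sensor Hpcal4 by -1.04 and the adenylyl cyclase Adcy4 by -0.85 (adjusted p = 0.0476 for each).

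In all, 24 of 18242 genes passed for early life against peripubertal, 11 higher and 13 lower. An unadjusted p under 0.05 was reached by 3532 genes, where 912 would reach it by chance if genes were independent. The highest other split of these samples gave 2361. A fit of only the 8 samples on this slide called 66. The dim spots around the higher genes were brighter in early life by a mean of 0.28 (SD 0.22, permutation p = 0.0002), and those around the lower genes differed by 0.046 (SD 0.19, permutation p = 0.72), with 7 of 13 in the direction of the gene's change. Without spots in raised or lowered patches, Olfr1219, Nox4 and Trmo had no estimate at a limit of 0.3, and Ulbp1 and Bpifb9b had none at 0.2. At 0.3, 10 of the other 13 genes under the naming rule passed. The calls of Sdc3, Vmn1r211 and Hpcal4 ended with 10 channels left and a larger SE, at -1.25 (SE 0.23) from -1.18 (SE 0.18), 1.65 (SE 0.31) from 1.55 (SE 0.24) and -0.86 (SE 0.19) from -1.04 (SE 0.17). Other kept probes differed by -0.02 for Trmo, 0.13 for Cltrn and -0.41 for Hpcal4. With the software's processed signals that probe of Trmo stood for the gene and gave -0.30. Probes too dim to be kept differed by 0.17 and 0.10 for Nox4, -0.16 for Ulbp1, -0.45 for Erfe, -0.29 for Plet1 and -0.17 for Plxna4. The count became 11, 9, 242 and 6 without control 1, 2, 3 or 4, became 12, 753 and 10 without early life 2, 3 or 4, and became 9 and 10 without peripubertal 1 or 4. It was 1 among genes well above background in all 12 channels, and the split of higher to lower moved to 14 and 6 with processed signals, 9 and 7 with quantile scaling and 6 and 0 with median centring.

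The erythroid, complement, MHC, macrophage and endothelial lists were lower in early life than in peripubertal samples by the list test with the preset correlation. Other lists of blood and immune cells did not pass, with medians of -0.06 for lymphocyte (3 of 7 genes positive, camera adjusted p = 0.677) and -0.81 for neutrophil genes (3 of 9 positive, camera adjusted p = 0.744). The mean of the lymphocyte genes was positive (0.20), and with fry that list went up (adjusted p = 0.314). All 10 erythroid genes were negative with a median of -1.68 (camera adjusted p = 0.000448; adjusted p = 0.901 with an estimated correlation), with Alas2, the enzyme of heme synthesis in red cells, at -2.23, Hbb-b2 at -2.10, Hbb-bt at -2.09 and Hba-a1 at -2.02. Globin genes are similar in sequence, and sharing of signal between their probes was not tested. Of 12 complement genes 11 were negative with a median of -0.71 (camera adjusted p = 0.00162; adjusted p = 0.901 with an estimated correlation), with C4b at -1.21, C1s1 at -0.99, C1qa at -0.95 and C1qb at -0.68. Of 15 MHC genes 14 were negative with a median of -0.48 (camera adjusted p = 0.00368; adjusted p = 0.901 with an estimated correlation), with H2-DMa at -1.13, H2-Eb1 at -1.11 and the peptide transporter genes Tap1 at -0.91 and Tap2 at -0.79. H2-Eb1 and Tap2 have values in 2 peripubertal samples only. Of 14 macrophage genes 13 were negative with a median of -0.63 (camera adjusted p = 0.0107; adjusted p = 0.901 with an estimated correlation). The protease gene Ctss stood at -1.45, from 2 peripubertal samples, and the exception was Cd14, a receptor for bacterial lipopolysaccharide, at 1.18. The C1q genes belong to both the macrophage and the complement lists. Of 13 endothelial genes 9 were negative with a median of -0.37 (camera adjusted p = 0.0469; adjusted p = 0.901 with an estimated correlation), with Esam at -0.65, Tek at -0.65, Tie1 at -0.63 and Robo4 at -0.55. The positive members were Kdr at 0.76, Cdh5 at 0.19, Ehd3 at 0.10 and Cldn5 at 0.07.

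A pair of lists were higher in early life than in peripubertal samples. Of 23 cell cycle genes 21 were positive with a median of 0.37 (camera adjusted p = 0.0107; adjusted p = 0.901 with an estimated correlation), with the spindle motor Kif11 at least 2.91-fold higher, Ccna2 at 0.92, Nusap1 at 0.55 and Bub1b at 0.40. Kif11 stood at 9.75 and 9.14 in early life 1 and 2, which share an array, and at 7.71 and 7.29 in early life 3 and 4. For Ccna2 these values were 10.04 and 9.61 against 8.65 and 8.47. Of 20 immediate early genes 15 were positive with a median of 0.75 (camera adjusted p = 0.0276; adjusted p = 0.901 with an estimated correlation), with the activity-induced genes Npas4 at 2.51 and Arc at 1.91, the phosphatase Dusp1 at 1.59 from 2 early life samples and Zfp36 at 0.79. No member of these 7 lists passed over all genes. Adjusted over the list alone, 6 erythroid, 3 complement and 4 MHC genes were lower, 3 macrophage genes were lower and 1 higher, and 0 endothelial, cell cycle or immediate early genes passed. At an unadjusted p under 0.05, 0 of all 46 lists passed with an estimated correlation and 6 with fry. With fry the adjusted p was 0.314 for the erythroid list and between 0.350 and 0.379 for the others. A score per animal gave a difference of -1.45 for erythroid genes and -0.72 for complement, each with an exact permutation p = 0.0286, the smallest that 70 regroupings allow, and an adjusted p = 0.152 over 16 measures. For the other 5 lists the exact permutation p was 0.143 (macrophage), 0.171 (endothelial), 0.0857 (MHC) and 0.0571 (cell cycle and immediate early). Regroupings treat array-mates as independent, and only 3 of the 35 splits keep them together, too few for a p under 0.05. The erythroid and complement lists passed in all 12 fits that left out 1 sample. The others failed at least once, with an adjusted p of up to 0.0506 for MHC without peripubertal 4, 0.110 for macrophage without peripubertal 3, 0.106 for cell cycle without early life 2, 0.156 for immediate early without peripubertal 2 and 0.283 for endothelial without early life 3. The count of lists fell to 4 without peripubertal 2 or 3.

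**Figure D2:**
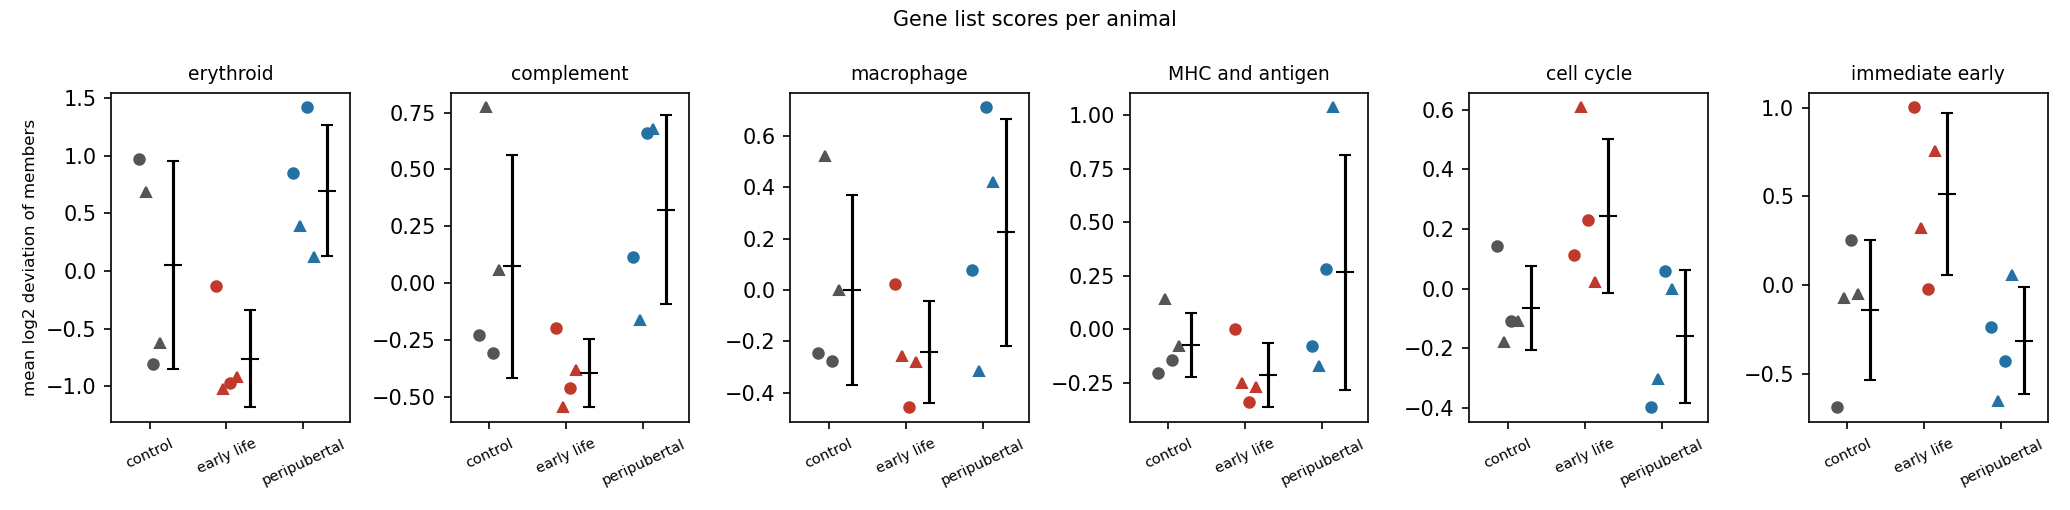
Mean log2 deviation of a list's members from their mean over all samples, per animal, for the erythroid, complement, macrophage, MHC and antigen, cell cycle and immediate early lists, with circles for Cy3, triangles for Cy5 and bars for the mean and SD. Erythroid scores average -0.76 in early life and 0.69 in peripubertal samples, and controls spread across both.

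Over all genes, the differences from control in early life and around puberty showed little common direction. Across 18197 genes the log2 differences from control had a Pearson r of 0.146 and a Spearman rho of 0.106, and 53.6% of genes had the same sign. Both differences share the control samples, and simulated groups with no change gave an r of 0.498 and 66.6% of genes with the same sign. With 1 control array for each comparison instead, r was -0.188 and 0.0518 for the possible assignments. These are correlations across genes, which are not independent replicates. The single gene called in both comparisons, ENSMUST00000139309, was lower in both. Both calls use the same controls, around whose spots the dim neighbours averaged 1.35, against -0.07 in early life and 0.21 in peripubertal samples. Without control 2, r was 0.246 and without control 3 it was 0.306.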

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

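The gene and list comparisons in this part were planned, as was the test on spots lost to outlier marks, and the other tests of explanations, including those without spots in patches, were chosen only after the result was seen.

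The value table and the scanner files place samples differently, and the series record codes the groups OC, OE and OP where the sample titles have PC, PE and PP. All 8 table columns of the deficient groups equal a channel that the scanner files place in the other deficient group. Early life columns 1, 2, 3 and 4 equal peripubertal channels 3, 4, 1 and 2. Peripubertal columns 1, 2, 3 and 4 equal early life channels 3, 4, 1 and 2. This fits a reversed order of the deficient groups' arrays in 1 of the records, and not only an exchange of group names. Which record is right cannot be told from the files. The 4 control columns equal no scanned channel, with at most 0.0399% of values equal, and 14 of 15 ovary markers were higher there than in the scanned controls, by a median log2 difference of 5.88, among them Cyp11a1 at 11.40, Hsd3b1 at 11.50, Zp3 at 6.82 and Gdf9 at 6.70, with Foxl2 at -0.20 as the exception. Foxl2 and Inha were also bright in the scanned controls, at 6.62 and 2.71 above the column median. In the same columns 0 of 10 pituitary markers were higher, with a median of -9.06 and Gh at -12.97 and Prl at -13.35. Ovary RNA is therefore a candidate source of the table's control columns, from a marker list written before its test but after the columns had been seen. No biological explanation of this mismatch was tested.

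Erythroid, complement and macrophage genes were lower in early life than in peripubertal samples by the list test with the preset correlation, but not with an estimated correlation (adjusted p = 0.901), and no member passed over all genes. Loss of spots to outlier marks is argued against by the 8 erythroid genes measured on every array, whose median log2 difference was -1.87 (SD 0.91). A lower share of all non-endocrine cells alike is argued against, as erythroid scores moved apart from the mean of the other such lists by -1.39 (SD 0.41, exact permutation p = 0.0286, adjusted p = 0.152 over 16 measures). That mean differed by -0.066 (SD 0.31), with macrophage scores at -0.47, endothelial at -0.27, oligodendrocyte at 0.29 and pericyte at 0.41. Complement scores differed by -0.72 (SD 0.31, exact permutation p = 0.0286, adjusted p = 0.152), past the bound set for less blood and nothing else. They cannot decide on it, since the C1q genes are shared with the macrophage list and the part of complement RNA from blood cells was not measured. Less blood as the whole cause or as a part of it stays open. Both score tests use the spread and the exact p. An earlier bound, an adjusted p under 0.05, was replaced after the values were seen, because 70 regroupings could hardly reach it. Under that bound neither score test would have decided. The regroupings treat array-mates as independent, and with whole arrays only 3 splits exist, too few for a p under 0.05. Perfusion or dissection differences and an effect of the diet's timing may both underlie the pattern and were not tested.

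The dim spots around genes called higher in early life than in control were brighter there too. They differed by 0.30 (SD 0.12, permutation p = 0.0001, the smallest that 10000 random sets can give), which is what raised patches would leave behind and could explain part of these calls. Some of these spots lie close together, and the test takes their overlapping neighbourhoods as independent. Without spots in such patches at a limit of 0.3, Ulbp1 kept all 12 channels and Bpifb9b 10, and both passed (adjusted p = 0.00931 and 0.0347). At a limit of 0.2 neither had an estimate, as the dim spots around each deviated by more on both early life arrays. Neighbours also went with the calls for genes higher in early life than in peripubertal samples, by 0.28 (SD 0.22, permutation p = 0.0002). For genes lower in early life than in control the mean of -0.27 (SD 0.61, permutation p = 0.0009) rests on Adam4 and the spot diagonal to it, ENSMUST00000139309, with 0.048 (SD 0.14) for the other 6. For genes lower in peripubertal samples than in control the mean of -0.31 (SD 0.56, permutation p = 0.0049) rests on ENSMUST00000139309 alone, with -0.033 (SD 0.050) for the other 3. Around the genes called lower in early life than in peripubertal samples the difference was 0.046 (SD 0.19, permutation p = 0.72), with 7 of 13 in the direction of their change, which decides nothing on patches. Among these, the neighbours of Sdc3 differed by -0.25 and those of Hpcal4 by -0.12, in the direction of the gene, and those of Tmsb10 by 0.45, against it. Without patches Sdc3 went from -1.18 (SE 0.18) to -1.25 (SE 0.23) and Hpcal4 from -1.04 (SE 0.17) to -0.86 (SE 0.19), and their calls ended with 10 channels left and a larger SE (adjusted p = 0.0634 and 0.0847). A change of the RNA itself could be judged only from 3 other kept probes of called genes, of which 0 showed over 50% of the change, too few to decide. An effect of the diet on these genes remains open and untested.

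Other splits of the samples bear on each count of genes. For early life against control, 4 of the 35 splits of the 8 samples called as many genes as the real 18, with 477 in the highest other split, so chance cannot be excluded. That split exchanges control 3 and early life 3, whose omission each raised the count too, and separates array-mates, unlike the real one. Exchanging control 3 with early life 1, 2 or 4 instead called 18, 4 and 1 genes. What gave the high count was not tested. At an unadjusted p under 0.05, 3 of these 35 splits had as many genes as the real 2971, with 4287 in the highest other. For peripubertal against control 1 of 35 did, the real split with 4 genes, against 2 in the highest other, but 11 of 35 had as many genes at an unadjusted p under 0.05 as the real 880, with 2248 in the highest other. For early life against peripubertal 1 of 35 did, with 24 genes against 2. For early life against peripubertal chance can be excluded only if array-mates are taken as independent. For peripubertal against control it is not excluded even then, as 880 also lies under the 939 genes that chance would give. Only 3 of the 35 splits keep array-mates together, too few for a share under 0.05, with highest other counts of 2, 2 and 0 in the order of the comparisons.

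Single samples stood apart from the other 3 of their group in 13 of 241 groups tested by Dixon's criterion, where chance gives about 5%. Those in control included Erfe at 7.60 and Cfap161 at 7.92 in control 3, B2m at 13.36 in control 4 and Pfkm at 12.64 in control 1. In early life they were Vdr at 10.09 in sample 1, Sdc3 at 9.95 in sample 4, Robo4 at 10.26 in sample 3 and the erythroid score at -0.13 in sample 1. In peripubertal samples they were Olfr1219 at 6.94 in sample 1 and Tap1 at 8.99, Gbp2 at 11.80 and Gpi1 at 14.89 in sample 4.

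Early life and peripubertal samples differed by the direct test for 16 genes under the naming rule. Among them the log2 differences were 2.82 for Trmo, 2.36 for Olfr1219, 2.21 for Bpifb9b, 2.18 for Nox4, 1.93 for Ulbp1, 1.55 for Vmn1r211 and 1.29 for Cltrn. In the first 6 of these no peripubertal sample was well above background, so these values are not exact and the folds are known only as lower bounds, from 2.63-fold for Vmn1r211 to 6.72-fold for Trmo. With processed signals another probe stood for Trmo, and its difference reversed to -0.30. They were -0.85 for Adcy4, -0.99 for Plet1, -1.04 for Hpcal4, -1.09 for Plxna4, -1.18 for Sdc3, -1.42 for Cfap161, -1.43 for Tmsb10 and -1.46 for Erfe. No early life sample was well above background for Plet1 (at least 1.31-fold lower) and Erfe (at least 2.09-fold lower). By the list test with the preset correlation they also differed for 7 lists (adjusted p = 0.901 with an estimated correlation, 0 lists past the threshold with fry), with medians of -1.68 for erythroid, -0.71 for complement, -0.63 for macrophage, -0.48 for MHC, -0.37 for endothelial, 0.37 for cell cycle and 0.75 for immediate early genes.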

How the results depend on the processing

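Alternatives chosen after seeing the data were the value table's transformation, the exchange of the deficient groups, the omission of spots in patches at limits of 0.2, 0.3 and 0.5, the fit of the list tests to the slide of the deficient groups, and the omission of single samples for the shared direction. The value table was not run for comparisons with control, as its control columns equal no scanned channel. Causes were not tested unless one is named. Of 29 named gene results past the threshold, 4 passed under every alternative that was run for single genes and gave a value, namely Olfr1219 in both of its comparisons and Nox4 and Ulbp1 for early life against peripubertal. The alternatives aimed at patches and dim spots are among those that gave them no value. Olfr1219 and Nox4 had none without patches at the limit of 0.3, and Ulbp1 had none at 0.2. None of these genes was well above background in all 12 channels. The exchange of the groups was run for counts of genes only, and would turn the sign of each difference between the deficient groups. Over 491 alternatives, 349 left such results past the threshold, 140 did not and 2 reversed. For 72 results not past it, 25 of 1292 alternatives brought them past and 10 reversed. For 11 lists, 202 of 282 alternatives kept the call, 78 lost it and 2 reversed. Single samples were left out for named genes only where they had passed. Without a whole array, a group rests on 1 array, whose variation was assumed to be like that of the others. Probe means take the probes with a value in each sample, so spots marked as outliers change which probes are averaged.

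For early life against control the 18 genes became 67 at an adjusted p of 0.1, 4 with median centring, 0 with all 12 channels well above background (fewer genes tested), 125 with probe means, 605 without the array block, 50 with a separate-channel fit, 30 without the dye term, 10 with a replicate block, 11 with only the 8 samples, 29 (20 higher, 9 lower) with the table's transformation and 4 with the groups exchanged. Without whole arrays they became 33 (control 1 and 2), 48 (control 3 and 4), 137 (early life 1 and 2) and 1931 (early life 3 and 4), and without single samples they ran from 6 to 280. The count stayed within 1.5 times under processed signals (27), no background correction (24), offset 16 (22), quantile scaling (21), no filter (16), array means (13), a robust prior (22) and omitted patches (14, 13 and 17 by rising limit).

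For peripubertal against control the 4 genes became 7 at an adjusted p of 0.1, with processed signals and with a separate-channel fit, 0 with offset 16, quantile scaling, median centring, no filter, all 12 channels, array means and a replicate block, 20 with probe means and without the array block, 10 (7 higher, 3 lower) with only the 8 samples, 2 with the table's transformation and 18 with the groups exchanged. Without whole arrays they became 23 (control 1 and 2), 7 (control 3 and 4), 20 (early life 1 and 2), 0 (early life 3 and 4), 36 (peripubertal 1 and 2) and 32 (peripubertal 3 and 4), and without single samples they ran from 0 to 3.

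For early life against peripubertal the 24 genes became 233 at an adjusted p of 0.1, 56 with offset 16 and with a robust prior, 6 with median centring and with a replicate block, 1 with all 12 channels, 151 with probe means, 1324 without the array block, 39 with array means, 189 with a separate-channel fit, 89 without the dye term, 66 with only the 8 samples, 76 with the value table under its own labels and 46, 52 and 57 without patches. Without whole arrays they became 10 and 120 (control), 161 and 2379 (early life) and 62 and 48 (peripubertal), and without single samples they ran from 6 to 753. The table's transformation gave 31 (21 higher, 10 lower).

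Of the lists, 0 for early life against control became 1 with processed signals, 6 without control 3 and 4, and 1 without early life 1 and 2, with a range of 0 to 7 without single samples. The 4 lists for peripubertal against control became 0 with an estimated correlation and with fry, 1 without control 3 and 4, 8 without peripubertal 1 and 2 and 0 without peripubertal 3 and 4, with a range of 1 to 8. The 7 for early life against peripubertal became 0 with an estimated correlation and with fry, 1 without early life 3 and 4 and 3 without peripubertal 3 and 4, with a range of 4 to 10, and 10 on the slide of the deficient groups. The erythroid list for peripubertal against control turned direction by its test without control 3 and 4 (median 0.034), and the MHC list without peripubertal 3 and 4 (median -0.11). The shared direction, r of 0.146, became -0.188 and 0.0518 with split controls and 0.230 without the filter, with a range of 0.103 to 0.306.

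Trmo reversed to -0.69 against control and -0.30 against peripubertal with processed signals, because another probe was the brighter there. With median centring Lhb became 0.24 against control, Pomc 0.085 for early life against peripubertal (0.097 with the value table) and Cga 0.40 and 0.19 for early life against control and peripubertal. Cga also became 0.16, 0.26 and -0.11 in the 3 comparisons with processed signals, 0.021 against control with quantile scaling and 0.15 against peripubertal with the value table. With probe means it became -2.80 and -2.93 for early life against control and peripubertal, without passing. There the mean in early life 1 and 2 lacked the brightest probe, so unlike sets of probes were compared. Median centring moved the median of all genes to 0.17 and 0.14 against control, from 0.03 and 0.01, and gave Gh differences of 0.40, -0.15 and 0.55 in place of 0.00, -0.22 and 0.22. Replicate numbers did not pair the samples, since 0 of the 12 pairs with the same number had a residual correlation over 0.1, with values from -0.285 to 0.0595. The fit that kept only the 8 samples left Vdr at 1.14 (adjusted p = 0.250) against control and 0.88 (adjusted p = 0.133) against peripubertal. With all 12 channels required to be well above background, 0, 0 and 1 genes passed. That fit dropped genes near background in some samples, and its counts do not tell this apart from calls lost on brighter genes.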

Other observations

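Some lists had lower scores in early life without passing. Of 20 cholesterol synthesis genes 16 were lower than in control, with a median of -0.30, and 13 were lower than in peripubertal samples, with a median of -0.20 (camera adjusted p = 0.0662). Scores of this list averaged -0.23 ± 0.08 (SD, n = 4) in early life, 0.12 ± 0.23 in control and 0.10 ± 0.10 in peripubertal samples. Scores of estrogen-responsive genes averaged -0.30 ± 0.08 in early life, 0.13 ± 0.22 in control and 0.15 ± 0.14 in peripubertal samples, but only 9 of 16 genes were lower in each comparison, with medians of -0.34 and -0.16, and the list did not pass (camera adjusted p = 0.201 against control, 0.213 against peripubertal). Adjusted over the list alone, 4 estrogen-responsive genes were lower and 2 higher against control, and 6 were lower and 3 higher against peripubertal.

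The median signal of spiked-in control RNA was higher on the slide of the controls in each dye. In Cy3 it was 7464 and 8665 in control samples and ran from 2622 to 4693 on the other slide, and in Cy5 it was 11944 and 10664 against 5168 to 7594. The median signal of all spots went the other way in Cy3, at 143 and 130 in control and from 146 to 188 in the others, and overlapped in Cy5, at 239 and 238 against 212 to 270.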
